A study of Citrus reticulata and Citrus x limon
Citrus reticulata
Citrus limon x Citrus reticulata and Citrus x limon and Citrus limon x Citrus reticulata with 9 samples.

How the data were processed

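Fruits were sampled 225 days after anthesis from Willowleaf mandarin, Eureka lemon and the allotetraploid somatic hybrid of both, a plant made by fusing cells so that it carries the chromosome sets of both parents. Total RNA from each sample (40 ug) was labelled with Cy3 and hybridised to a 2-colour citrus cDNA array together with a Cy5-labelled common reference, an equimolar mix of all samples. There were 9 arrays, 3 per group, with no dye swap, so a dye effect of a probe that is the same on every array cancels between groups and one that varies does not. The labels give 3 replicas per genotype and 3 field trees per genotype on 1 rootstock, without saying that 1 replica is 1 tree. Lemon homogenates were brought to neutral pH with NaOH, a step the labels give for lemon only. The labels name the fruit and no tissue of it.

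Per the file headers, the authors scanned the arrays at 635 nm (Cy5) and 532 nm (Cy3) and read the spots with GenePix Pro 6.1.0.4. The deposited spot values are linear scanner intensity, as foreground and local background medians, means and SDs, without normalization. A spot flag is a deposited quality score, with -100 for bad, -75 for absent and -50 for not found. Each array held 22176 spots, of which 691 were controls, and 21271 clones, of which 16335 carried a gene description. The deposited matrix, another kind of file, holds 9374 probes. In 99.3% of its values it equalled, within 0.0006, the authors' ratio of background-subtracted medians, 635 over 532 nm, with no centring. It was therefore used only as an alternative, after turning it to sample over reference. On 8 arrays 8767 to 10519 spots were flagged bad (39.5% to 47.4%), and on mandarin 1 1378 spots. The array list marks 1017 spots whose PCR gave no product or a double band. Of these, 99.1% to 99.6% were flagged bad on the 8 arrays and 4.62% on mandarin 1, and 4 such clones were tested.

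Analysis was done in R 4.3.3 with limma 3.58.1 and statmod 1.5.0. Foreground medians were background-corrected by normexp with an offset of 50. Log2 ratios of sample Cy3 over reference Cy5 were normalised within each array by a global loess with control spots at weight 0, and spots of the same clone were averaged. The channels are those of the labels, and the values make them doubtful. An equimolar mix holds each group's own RNA, so no group can lie far above it. Yet means reached 4.77 in mandarin (pectin methylesterase, lemon -1.20) and 4.07 in lemon (CPN60, mandarin -0.44). If Cy5 held the samples, every higher and lower given here turns round. Which channel held them was not tested. The offset and the loess shrink ratios: on simulated arrays a true log2 ratio of 2 came out at a median of 1.51 and one of -2 at -1.4, over 231 probes, 99.6% of them with the right sign. Folds are therefore understated. A probe was tested when, on all arrays of at least 1 group, its Cy3 foreground lay more than 2 background SDs above background and it had a usable spot on at least 2 arrays of every group. Spots flagged bad or absent were not usable, and those flagged not found were kept. This left 11717 probes for 11596 unigenes, 9446 of them described and 9488 with values on all 9 arrays.

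Array depth is given as signal over background. The median Cy3 signal was 2.708 to 4.868 times background, 61.57% to 72.54% of spots were well above background in Cy3, and 0 to 144 spots per array were saturated in Cy3. The number of arrays limits the precision. A cDNA probe can bind transcripts of related genes and of both parents' alleles, so the values are per probe and do not separate the mandarin and lemon copies in the hybrid. Gene names are those of the array's clone list, which names genes by similarity, and the files give no genome positions.

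One limma model (lmFit and eBayes) with the 3 groups gave 4 comparisons: mandarin with lemon, hybrid with mandarin, hybrid with lemon, and hybrid with the mid-parent, the mean of both parents' log2 values. Adjusted p-values are Benjamini-Hochberg over all probes tested, with a threshold of 0.05. For probes called between the parents, fry tested whether the hybrid lay below the mid-parent and, with each probe signed by its parental difference, whether it lay nearer to mandarin than to lemon, on the 364 of 403 probes with values on all 9 arrays. This contrast is orthogonal to the one that chose the probes. The hybrid arrays still helped to choose them, through the spread that all 9 arrays share in the fit, so the choice was not free of the hybrid. A total of 18 gene lists, matched by text to the names, were tested by camera with a preset correlation of 0.01, with Benjamini-Hochberg over the lists within each comparison, and again with an estimated correlation. They were organic acid metabolism, proton pumps and acid transport, sugar, carotenoid and isoprenoid precursors, flavonoid and phenylpropanoid, terpenes and aroma, cell wall, ascorbate and redox, hormones, heat shock and water stress, defence proteins, ribosome and translation, chromatin and small RNA, photosynthesis, seed, epidermis and cuticle, vascular tissue, and housekeeping. Photosynthesis, seed, epidermis and vascular tissue served as markers of tissues a fruit sample could hold.

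Named genes followed a rule. Per comparison they were the 8 largest rises and 8 largest falls among called, named probes whose 3 values in 1 group all lay beyond the 3 of the other, with 1 probe per gene. The script compared the values present, so 1 gene named, cyclic nucleotide-gated ion channel 1 in hybrid with lemon, had 2 lemon values and departs from the rule. For each list the rule added the 2 members with the smallest p between the parents and the 1 with the smallest p against the mid-parent. Where no probe was called, it took the 3 smallest p in each direction. Genes named outside it are said to be chosen after their values were seen. The model, lists, rule and first set of alternatives were fixed before the data were examined.

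The steps were tested on simulated data, in 5 runs with 200 changed probes each among 11717. Between mandarin and lemon they recovered 12.8% of true 2-fold changes, 84% of 4-fold, 95.2% of 8-fold and 99.2% of 16-fold changes, with 5.82% false calls. Between hybrid and mandarin they recovered 0.8% of 2-fold and 64% of 4-fold changes, with 8.55% false calls, and against the mid-parent 4.8% and 68.8%, with 7.06% false calls. The simulation assumed replicates that all vary alike.

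Alternatives were no background correction, foreground means, print-tip loess, median centring, scale normalization between arrays, no filter on dim probes, a filter for signal on all 9 arrays, all negative flags left out, the authors' values, array weights, the replicate number as a block, scan day as a block, fits with only the groups compared, a 2-fold minimum, an adjusted p under 0.01, a linear mid-parent, and leaving out each array in turn. After the data were seen, 4 were added: all flags ignored, lemon 1 and hybrid 3 left out together, list patterns matched only from the start of a word, and, for the shares, hybrid 2 and the set of probes changed apart. The files give 3 scan days on 2 scanner models. Day 1 held mandarin 1, lemon 1 and lemon 2, day 2 mandarin 3, lemon 3 and hybrid 1, and day 3 mandarin 2, hybrid 2 and hybrid 3. Other columns of the spot files and the control spots were left out of the comparisons.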

Results

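The data are 9 arrays of fruit RNA, 3 each from Willowleaf mandarin, Eureka lemon and their allotetraploid somatic hybrid. Values are log2 ratios of the sample to a common reference by the labelled channels, compared for 11717 probes. Group means far above the mix, given above, argue against these channels, so each higher or lower below is probably reversed. On the log2 scale, which parent the hybrid lay nearer to does not depend on this. The median Cy3 signal minus background ran from 299 on lemon 1 to 1079 on hybrid 1. The SD of log2 ratios was 1.05 on lemon 1 and 0.81 on hybrid 3, and 0.36 to 0.65 on the other 7 arrays. Differences between groups are given on the log2 scale with the SE of the limma fit and n = 3 arrays per group unless another n is given. Group means are given with their SD. The p-values measure the spread between these samples, since the labels do not say that the replicas are separate trees.

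The arrays of a group did not always resemble each other most. Across probes, which are not independent replicates, hybrid 2 correlated at r = 0.65, 0.52 and 0.61 with mandarin 1, 2 and 3, and at -0.21 and -0.02 with hybrid 1 and hybrid 3. Lemon 1 correlated at 0.66 with hybrid 3, and at 0.31 and 0.15 with lemon 2 and lemon 3. Lemon 2 and lemon 3 correlated at 0.68, and the mandarin arrays at 0.39 to 0.52. These patterns bear on every comparison with the hybrid.

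**Figure D1:**
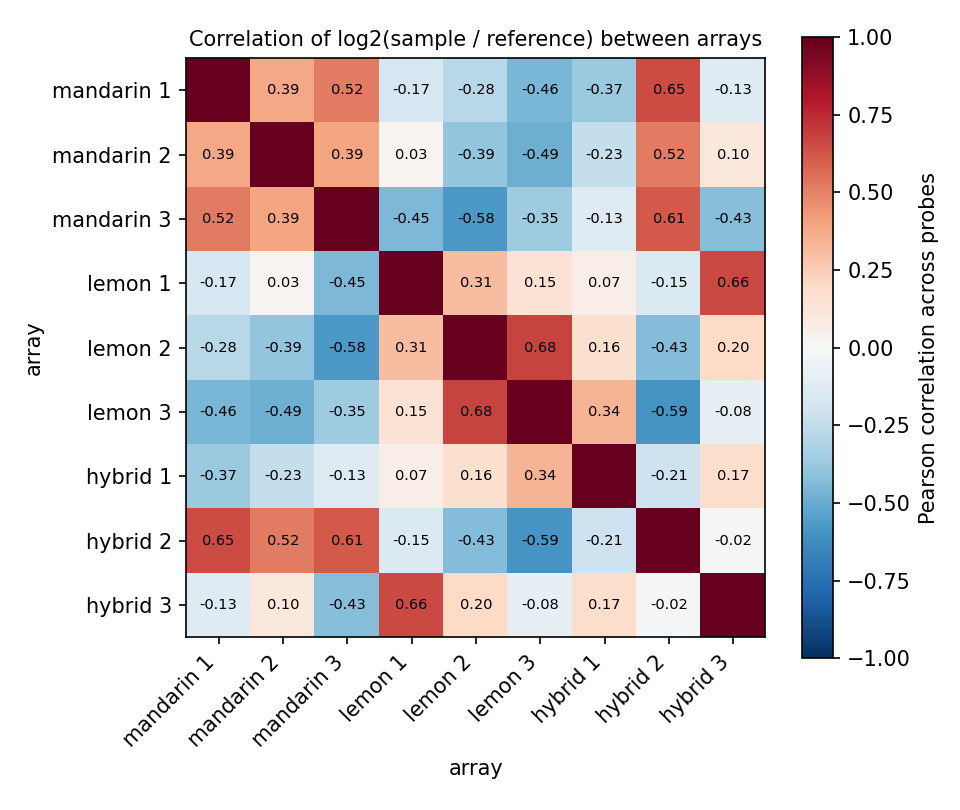
Pearson correlation, across the probes with values on both arrays, of the log2 ratio of sample to common reference, for each pair of the 9 arrays (3 mandarin, 3 lemon, 3 hybrid); both axes list the arrays. Hybrid 2 correlated at 0.52 to 0.65 with the mandarin arrays and hybrid 3 at 0.66 with lemon 1.

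The mandarin and lemon fruits were compared to find the genes whose expression the hybrid could inherit from parents that differ. By the labelled channels, mandarin fruit had far more signal for a pectin methylesterase, an enzyme that modifies cell wall pectin, and for single genes of flavonoid synthesis and of the photosystems, such as flavanone 3-hydroxylase and photosystem I subunit XI. Most probes of both lists did not pass (58 of 72 and 50 of 56). The pectin methylesterase precursor (probe C08033H07) was higher in mandarin by 5.97 ± 0.93, a 62.8-fold difference (adjusted p = 0.0145), with means of 4.77 ± 1.25 in mandarin and -1.20 ± 0.39 in lemon. A protein similar to chalcone-flavonone isomerase (C02004H09), an early enzyme of the flavonoid pathway, was higher by 5.42 ± 0.60 (42.8-fold, adjusted p = 0.00526). Lemon fruit had, by the same channels, more signal for limonene synthases, which make the main monoterpene of citrus oil, for sucrose-phosphate synthase 1, an enzyme of sucrose synthesis, and for the mitochondrial chaperonin CPN60. These 3 lay at -3.34 ± 0.47 for (R)-limonene synthase 1 (10.1-fold, adjusted p = 0.0129), -4.73 ± 0.85 for sucrose-phosphate synthase 1 (26.5-fold, adjusted p = 0.0248) and -4.51 ± 0.43 for CPN60 (22.8-fold, adjusted p = 0.00458).

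Among the 8 largest rises and 8 largest falls, all 3 values of 1 parent lay beyond all 3 of the other, by construction of the rule. The remaining rises with a gene name were photosystem I subunit XI (4.37 ± 0.60), flavanone 3-hydroxylase (4.33 ± 0.70), a peroxidase precursor (3.92 ± 0.80) and NADH-plastoquinone oxidoreductase subunit 3 (3.49 ± 0.46). The remaining falls were vignain precursor, a cysteine protease (-4.79 ± 0.97), a gamma-thionin (-4.75 ± 0.90), harpin inducing protein 1-like 9 (-4.59 ± 0.73), seed specific protein Bn15D18B (-4.51 ± 0.67) and hydroxyisourate hydrolase (-4.45 ± 0.74). Adjusted p for these ran from 0.00881 to 0.0341. A further 2 rises (C06009D01 and C31403G05) and 1 fall (C31808G10) belonged to probes described only by the name of a predicted protein of another plant.

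Of 72 probes of the flavonoid and phenylpropanoid list, 10 were higher in mandarin, 4 were lower and 58 did not pass, and 32 were called when adjusted over the list alone. The higher ones included chalcone synthase 1 (2.92 ± 0.50), which makes the chalcone skeleton, flavonoid-3'-hydroxylase (2.53 ± 0.50), phenylalanine ammonia-lyase (1.98 ± 0.32), the entry enzyme of the pathway, and a hydroxycinnamoyl transferase (C32105G01, 3.19 ± 0.36). The lower ones were an isoflavone reductase-like protein, a second hydroxycinnamoyl transferase (C06020B01), hydroxycinnamoyl CoA quinate transferase (-2.73 ± 0.48) and cinnamyl-alcohol dehydrogenase 1. The list as a whole was not called by camera (adjusted p = 0.172).

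Photosynthesis probes were, by the labelled channels, higher in mandarin as a list, with a median of 0.34 over 56 members (adjusted p = 0.0051), a call that was lost with an estimated correlation (adjusted p = 0.565). Of its members 6 were higher, 0 lower and 50 did not pass, and 12 were called when adjusted over the list alone. They included photosystem I reaction center subunit VI (3.09 ± 0.21, adjusted p = 0.00109), chlorophyll a-b binding protein 151 (3.30 ± 0.28, adjusted p = 0.00242), which binds chlorophyll in the light-harvesting antenna, and oxygen evolving enhancer protein 1 (3.40 ± 0.46). The list's median was 0.20 within scan day 1 and 0.20 within scan day 2. On lemon 1 alone the photosynthesis median was 0.115, above 0.0498 on mandarin 1 and 0.0778 on mandarin 3. All probes of lemon 1 had a median of 0.152. The ribosome and translation list was also higher in mandarin, by a median of 0.11 over 301 members, of which 4 were higher, 0 lower and 297 did not pass, and 0 were called over the list alone (adjusted p = 0.0261). The call was lost with an estimated correlation (adjusted p = 0.565), without mandarin 3 (adjusted p = 0.0616) and without lemon 2 (adjusted p = 0.251). On lemon 1 the ribosome median was 0.108, within the 0.0481 to 0.113 of the mandarin arrays. Vascular tissue markers had a median of 0.81 over 14 members, none of which passed, alone or over the list (adjusted p = 0.0261; adjusted p = 0.551 with an estimated correlation). The vascular median rested on lemon 1: it was 0.85 within scan day 1, which has that array, 0.13 within scan day 2 and 0.22 without lemon 1 (adjusted p = 0.15). That call was also lost without mandarin 1 (adjusted p = 0.0894). The 2 vascular markers with the smallest p, both fasciclin-like arabinogalactan proteins, lay at 1.10 ± 0.30 (adjusted p = 0.0758) and 1.54 ± 0.44 with 2 mandarin arrays (adjusted p = 0.0959).

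Genes of acid, sugar and terpene metabolism differed singly, and their lists were not called. Of 64 organic acid probes, phosphoenolpyruvate carboxylase kinase 2 was higher in mandarin (2.68 ± 0.42) and cytoplasmic aconitate hydratase, which turns citrate into isocitrate, was lower (-1.30 ± 0.29). Adjusted over the list alone 6 were called. Of 40 proton pump and acid transport probes, an inorganic pyrophosphatase was lower (-1.48 ± 0.31), 3 were called over the list alone, and a plasma membrane H+ ATPase at -2.26 ± 0.54 did not pass (adjusted p = 0.0555). Of 69 sugar probes 3 were higher and 2 lower, 11 over the list alone. Sucrose synthase (1.98 ± 0.37) and vacuolar invertase (2.02 ± 0.46), which both break down sucrose, and a glucose-6-phosphate dehydrogenase were higher, and a sugar transporter (-2.44 ± 0.40) was lower with sucrose-phosphate synthase 1. Of 68 terpene and aroma probes 1 was higher and 4 lower, 12 over the list alone. The lower ones were (R)-limonene synthase 1, given above, D-limonene synthase (-2.91 ± 0.43), alcohol dehydrogenase (-4.12 ± 0.77) and cinnamyl-alcohol dehydrogenase 1 (-1.63 ± 0.35), and the higher one was another cinnamyl alcohol dehydrogenase (2.22 ± 0.40), of an enzyme family of lignin synthesis that the flavonoid list also holds. Of 33 carotenoid and isoprenoid precursor probes 4 were lower, 6 over the list alone. They were 2 probes of homogentisate geranylgeranyl transferase, an enzyme of vitamin E synthesis (C05068G03 at -3.12 ± 0.23, adjusted p = 0.00109, and C06053F09 at -2.18 ± 0.41), zeta-carotene desaturase (-1.16 ± 0.26) and 1-deoxy-D-xylulose-5-phosphate reductoisomerase (-1.07 ± 0.23).

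Of 137 cell wall probes 5 were higher and 4 lower, 14 over the list alone. A second pectin methylesterase, PME1, was higher (3.10 ± 0.34), and 2 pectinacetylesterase probes were lower (C06003F02 at -2.58 ± 0.48 and C34107F11 at -1.88 ± 0.36). Of 106 ascorbate and redox probes 4 were higher and 2 lower, 11 over the list alone. Both catalase probes called were higher (C31003C03 at 1.70 ± 0.39 and C31503D10 at 2.31 ± 0.48), and 1 glutathione S-transferase was higher (1.86 ± 0.35) while glutathione S-transferase T3 was lower (C32101A12, -2.37 ± 0.38). Of 84 hormone probes 4 were higher and 2 lower, 9 over the list alone. Auxin response factor 10 was higher (2.17 ± 0.39) and auxin response factor 8 lower (-2.54 ± 0.47). Of 122 heat shock and water stress probes 2 were higher and 3 lower, 8 over the list alone, with a heat shock transcription factor at 2.26 ± 0.34 and a chloroplast dnaJ 20 at 1.60 ± 0.29. Of 60 defence probes miraculin-like protein 3 was lower (-3.76 ± 0.58) and miraculin-like protein 2 at -2.10 ± 0.53, with 2 lemon arrays, did not pass (adjusted p = 0.0707), 1 over the list alone. Of 35 chromatin and small RNA probes an argonaute-like protein, of the family that binds small RNAs, was lower (C20008F05, -3.23 ± 0.39), 1 over the list alone. Of 19 epidermis and cuticle probes 3 were higher and 0 lower, 8 over the list alone, namely 2 lipid transfer proteins (C07010C08 at 3.22 ± 0.48 and C34103D10 at 2.13 ± 0.42) and a fatty acid elongase (2.62 ± 0.51). No seed marker of the list passed among 8, 0 over the list alone, though the list's text pattern missed seed specific protein Bn15D18B, a called fall named above. The 2 with the smallest p were seed maturation-like protein (-0.97 ± 0.29) and seed maturation protein PM37 (0.59 ± 0.33). Of 124 housekeeping probes 2 were higher, 2 over the list alone: tubulin beta-1 chain (1.65 ± 0.28) and a protein that interacts with poly(A)-binding protein (1.81 ± 0.34), which its text pattern placed there and which is no housekeeping standard. Adjusted p of the 15 lists not called ran from 0.151 to 0.911.

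In all, 403 of 11717 probes differed between mandarin and lemon (152 higher and 251 lower in mandarin, against 153 and 134 with scale normalization between arrays and 218 and 258 with all flags ignored), and 2406 had an unadjusted p under 0.05, where chance gives 586. With the channels turned, higher and lower change places and the total stays. Within scan day 1 and within scan day 2 all 403 and all 398 probes with a value kept their sign, with medians of 1.79 and 1.96 in the called direction, although the probes were chosen on these arrays. With scan day as a block 71 were called. The count was 61 without mandarin 1, 48 without mandarin 2, 46 without mandarin 3, 472 without lemon 1, 122 without lemon 2, 99 without lemon 3, 372 without hybrid 1, 699 without hybrid 2 and 510 without hybrid 3.

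The hybrid and lemon fruits were compared to find where the hybrid departs from the lemon parent. Among single genes, and by the labelled channels, the hybrid had more signal than lemon for chlorophyll a-b binding protein 151, photosystem I reaction center subunit VI and chalcone synthase 1, and less for 2 limonene synthase probes, CPN60 and homogentisate geranylgeranyl transferase. Chlorophyll a-b binding protein 151 was higher by 3.31 ± 0.28 (9.92-fold, adjusted p = 0.00176), with means of 1.86 ± 0.31 in the hybrid, 1.84 ± 0.46 in mandarin and -1.45 ± 0.08 in lemon. Photosystem I reaction center subunit VI was higher by 2.79 ± 0.21 (adjusted p = 0.00155) and a thylakoid membrane phosphoprotein of 14 kDa by 2.65 ± 0.23 (adjusted p = 0.00216). Homogentisate geranylgeranyl transferase (C05068G03) was lower by 9.44-fold (-3.24 ± 0.23, adjusted p = 0.00155), with means of -0.39 ± 0.18 in the hybrid, -0.27 ± 0.27 in mandarin and 2.85 ± 0.19 in lemon, and its second probe (C06053F09) lay at -2.54 ± 0.41. CPN60 was lower by 18-fold (-4.17 ± 0.43, adjusted p = 0.00565).

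The other rises named were the chalcone-flavonone isomerase-like protein (3.99 ± 0.60), chalcone synthase 1 (3.17 ± 0.50), a hydroxycinnamoyl transferase (2.74 ± 0.36) and the predicted proteins of C31207E11 and C31403G05. The other falls were miraculin-like protein 3 (-3.28 ± 0.58), a mitogen-activated protein kinase (-3.15 ± 0.44), (R)-limonene synthase 1 (-2.84 ± 0.47), cyclic nucleotide-gated ion channel 1 with 2 lemon arrays (-2.76 ± 0.28), glucosyltransferase NTGT4 (-2.71 ± 0.40) and male sterility protein 2 (-2.65 ± 0.46). Adjusted p for these ran from 0.00556 to 0.0419. Without hybrid 2, which resembled mandarin, 8 of these 16 named genes were still called. They were chlorophyll a-b binding protein 151 (3.28), photosystem I subunit VI (2.76), the thylakoid phosphoprotein (2.48), the isomerase-like protein (3.25), C31403G05 (2.94), homogentisate geranylgeranyl transferase (-3.28), CPN60 (-3.96) and the ion channel (-2.70). The other 8 missed the threshold with 1 array fewer (adjusted p from 0.0563 to 0.134) and kept their direction, at 2.62 to 3.28 for the rises and -2.94 to -2.35 for the falls.

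Of 56 photosynthesis probes 4 were higher in the hybrid, 0 lower and 52 did not pass, 12 over the list alone, with a list median of 0.17 (adjusted p = 0.000672; 0.497 as adjusted p with an estimated correlation). The ribosome and translation list had a median of 0.19, with 1 of 301 members higher, 0 over the list alone (adjusted p = 0.000184; adjusted p = 0.365 with an estimated correlation). Of 72 flavonoid and phenylpropanoid probes 4 were higher, 0 lower and 68 did not pass, 14 over the list alone, with a median of 0.12 (adjusted p = 0.0403; adjusted p = 0.417 with an estimated correlation). The vascular list, with 0 of 14 members called and 2 over the list alone, had a median of 0.40 (adjusted p = 0.0272; adjusted p = 0.365 with an estimated correlation). The flavonoid call ended without any 1 of mandarin 1, mandarin 2, lemon 1, lemon 2, lemon 3 or hybrid 3, at up to an adjusted p of 0.345, with scan day (adjusted p = 0.186) or the replicate number (adjusted p = 0.051) as a block and in 5 further alternatives, and the vascular call without mandarin 1, mandarin 2, lemon 1, hybrid 2 or hybrid 3, at up to 0.126. Within scan day 2 the 4 medians were 0.18, 0.26, 0.057 and 0.20, in the order given. In the other lists, 2 carotenoid, 2 terpene and 1 cell wall probe, the miraculin and an argonaute-like protein (-2.56 ± 0.39) were lower, and pectin methylesterase PME1 with 2 hybrid arrays (2.26 ± 0.38) was higher. Adjusted over the list alone there were 6 organic acid, 3 carotenoid, 3 cell wall, 2 terpene, 2 defence, 2 epidermis and 1 chromatin calls, and 0 in the remaining 7 lists. Adjusted p of the 14 lists not called ran from 0.0967 to 0.952. The terpene and proton pump lists had a median above 0 and a mean below it, and the seed list a median and mean above 0 with a test pointing down.

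In all, 89 probes differed between hybrid and lemon (27 higher and 62 lower in the hybrid), with 1571 at an unadjusted p under 0.05. Of these, 83 were also called between mandarin and lemon, each in the direction of mandarin (26 higher, 57 lower). Both comparisons share the lemon arrays. In 20 simulations of noise with no effect in any group, the 403 and 89 probes with the smallest p overlapped by 32.9 on average. These simulations hold no difference between the parents, so they do not give the overlap to be had here without a hybrid effect. Within scan day 2 all 89 kept their sign with a median of 1.99, although the probes were chosen on these arrays, and with scan day as a block 0 were called. Scale normalization between arrays also gave 0. The count was 16, 24 and 13 without mandarin 1, 2 and 3, 175, 11 and 10 without lemon 1, 2 and 3, and 45, 14 and 41 without hybrid 1, 2 and 3.

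**Figure D2:**
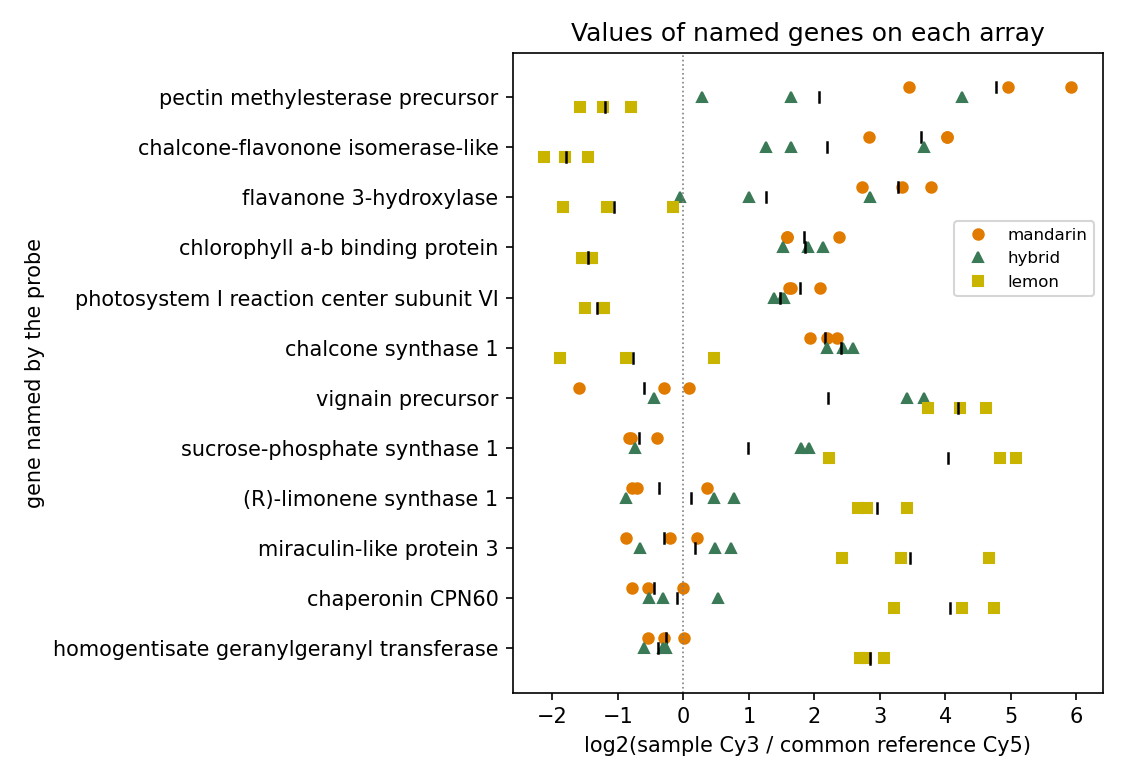
Log2 ratio of sample Cy3 to common reference Cy5 (horizontal axis) of 12 named genes, with 1 point per array for the 3 mandarin, 3 hybrid and 3 lemon arrays and a black tick at each group mean. For homogentisate geranylgeranyl transferase the hybrid mean of -0.39 lies by the mandarin mean of -0.27, far from the lemon mean of 2.85, while for vignain precursor hybrid 2 lies at -0.44 and the other hybrid arrays lie near lemon.

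The hybrid and mandarin fruits were compared to find where the hybrid departs from the mandarin parent. No gene passed the limma test. The named genes with the smallest p were thaumatin-like protein isoform 3, of a family of defence proteins, at 1.82 ± 0.40 with 3 mandarin and 3 hybrid arrays, a glucuronosyl transferase-like protein with 2 hybrid arrays at -1.97 ± 0.43, the transcription factor MADS5 with 2 mandarin arrays at -1.84 ± 0.43, and alpha-mannosidase with 2 arrays of each at -1.28 ± 0.30. The predicted proteins of IC0AAA70CG09 and, with 2 mandarin arrays, C31404H07 lay at 1.02 ± 0.23 and 1.55 ± 0.34. All 6 had an adjusted p of 0.921. The photosynthesis list lay at a median of -0.043, flavonoids at -0.0029, ribosome and translation at 0.044 and vascular markers at -0.035. Defence proteins had a median of 0.12 over 60 members (adjusted p = 0.227), and no list was called, with adjusted p from 0.227 to 0.878, nor any member over its list alone. Cell wall and ascorbate lists had a median below 0 and a mean above it, and the flavonoid list a median and mean below 0 with a test pointing up.

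A total of 0 probes were called between hybrid and mandarin, 597 had an unadjusted p under 0.05, where chance gives 586, and within scan days 2 and 3 and with scan day as a block 0 were called. This count rested on hybrid 2: without it 68 probes were called, 46 higher and 22 lower in the hybrid, all of them displaced toward lemon, and 63 of them also called between mandarin and lemon. Both comparisons share the mandarin arrays, which favours agreeing signs and shared calls. Without mandarin 2, hybrid 2 or hybrid 3 the defence list was called, with adjusted p of 0.00363, 0.0479 and 0.0346.

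The hybrid was compared with the mid-parent to find genes whose expression is not the mean of both parents. No gene passed against the log2 mid-parent. The closest was homogentisate geranylgeranyl transferase, 3.2-fold below the mid-parent by the labelled channels (-1.68 ± 0.20, adjusted p = 0.0653). Above the mid-parent lay the thylakoid membrane phosphoprotein of 14 kDa (1.47 ± 0.20, adjusted p = 0.155), chlorophyll a-b binding protein 151 (1.66 ± 0.24, adjusted p = 0.171) and photosystem I reaction center subunit VI (1.24 ± 0.18, adjusted p = 0.177). Cyclic nucleotide-gated ion channel 1 with 2 lemon arrays (-1.33 ± 0.23, adjusted p = 0.391) and plastid 3-keto-acyl-ACP synthase II-B (-1.22 ± 0.23, adjusted p = 0.508) lay below. For all 6 the hybrid mean lay nearer to the mandarin mean than to the lemon mean. Without hybrid 2 they lay at -1.72, 1.30, 1.63, 1.21, -1.27 and -1.32 in the order given (adjusted p from 0.167 to 0.275).

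The lists above the mid-parent were ribosome and translation (median 0.11, adjusted p = 0.000714), photosynthesis (median 0.082, adjusted p = 0.0176), cell wall (median 0.065, adjusted p = 0.045) and flavonoid and phenylpropanoid (median 0.096, adjusted p = 0.045), with 0, 3, 0 and 0 members called over the list alone. With an estimated correlation none was called, at adjusted p of 0.542, 0.677, 0.492 and 0.55. Without hybrid 2 the photosynthesis median turned to -0.011 (adjusted p = 0.0815), and that call also ended without mandarin 1, mandarin 3, lemon 3 or hybrid 3 (adjusted p up to 0.0938). The cell wall call ended without mandarin 2, mandarin 3, lemon 1, lemon 3, hybrid 1 or hybrid 3 (adjusted p up to 0.179), and the flavonoid call without any 1 array except hybrid 1 (adjusted p up to 0.513). With scan day as a block the photosynthesis and flavonoid calls ended (adjusted p = 0.626 and 0.487). Within scan day 2 the 4 medians were 0.155, 0.141, 0.172 and 0.0141. Each list's member with the smallest p did not pass: 30S ribosomal protein S31 with 2 lemon arrays lay at 0.98 ± 0.21, chalcone synthase 1 at 1.71 ± 0.43, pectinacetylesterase at -1.03 ± 0.31, (R)-limonene synthase 1 at -1.17 ± 0.41, a sugar transporter-like protein at -1.20 ± 0.30, glutamine synthetase with 2 lemon arrays at -0.89 ± 0.21, aquaporin PIP1.3 with 2 lemon arrays at 1.14 ± 0.32, and a chitinase-like protein with 2 arrays per group at 1.17 ± 0.24. Homogentisate geranylgeranyl transferase and chlorophyll a-b binding protein 151, given above, were those of the carotenoid and photosynthesis lists. The remaining 8 lay between -1.05 ± 0.37 for a ubiquitin-conjugating enzyme and 1.21 ± 0.37 for ethylene response factor ERF3b with 2 arrays per group. Adjusted p of the 14 lists not called ran from 0.1 to 0.939, with 2 carotenoid probes and no probe of the others called over the list alone. Median, mean and test did not share a sign for the organic acid, sugar, terpene, heat shock, chromatin, seed and epidermis lists.

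A total of 0 probes were called against the log2 mid-parent, 655 had an unadjusted p under 0.05, and against the linear mid-parent 2 were called, both lower. No leave-out of 1 array and no block of scan day gave a call.

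**Figure D3:**
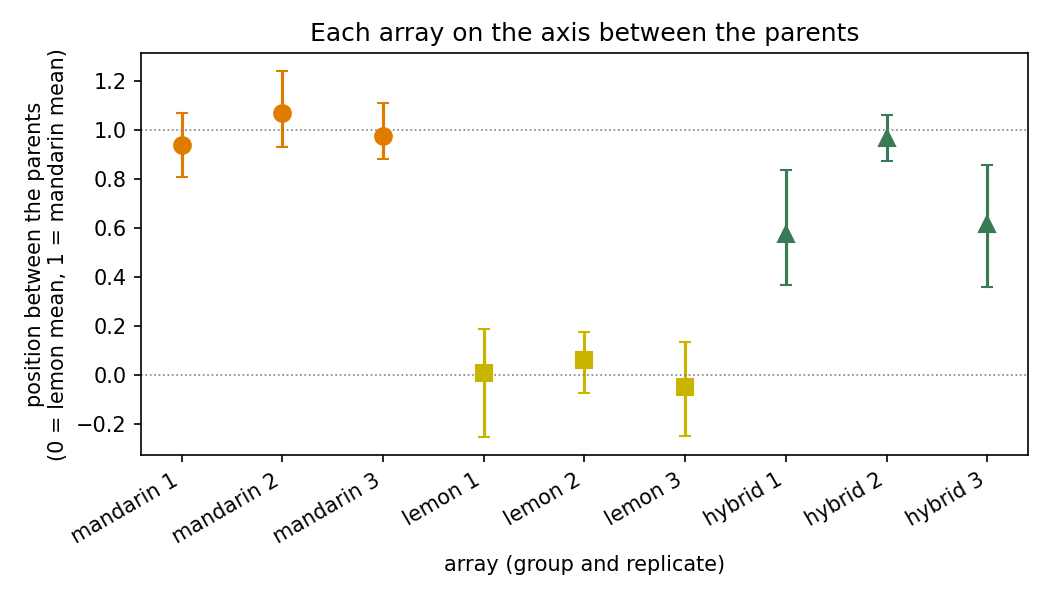
Median position of each of the 9 arrays over the probes called between the parents (up to 403), on an axis with the lemon mean at 0 and the mandarin mean at 1, by array; bars give the lower and upper quartile across probes. Hybrid 1 and hybrid 3 lie at 0.58 and 0.61, hybrid 2 at 0.97, and the mandarin arrays at 0.94 to 1.07.

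The 403 probes that differed between the parents show which parent the hybrid resembled. The median position of the hybrid was 0.73 on an axis from 0 (lemon) to 1 (mandarin), and 61 probes (15.1%) lay nearer to lemon. The lean toward mandarin passed fry at 0.05 on the 364 probes with values on all arrays, though the hybrid arrays helped to choose these probes through the shared spread. Hybrid 1 lay at 0.58, hybrid 3 at 0.61 and hybrid 2 at 0.97. The hybrid lay below the mid-parent for 242 probes (60%), against 51.5% of all probes tested, and the tests against the mid-parent passed at 0.05, by fry on the same 364 probes and by camera with either correlation. These are tests by model on 3 arrays per group. No exact test by splits was made, since only 100 of the possible splits were drawn and 6 of these called enough probes. Among the 251 probes higher in lemon, such as CPN60 and the limonene synthases, 86.1% were below the mid-parent, and among the 152 higher in mandarin 17.1%. The share below is thus no separate result. It goes with the lean toward mandarin and the larger number of called probes higher in lemon. With the channels turned, below would read above. Scan day 2, with 1 array per group, had 57.5% below and 38.4% nearer to lemon. Both shares depended on hybrid 2 and on the probes called, which change together when it is left out. Without it 699 probes were called between the parents, of which 49.4% were below the mid-parent and 57.2% nearer to lemon, neither past fry, with hybrids 1 and 3 at a median position of 0.44. Without it on the 399 of the 403 probes that kept values, 57.1% were below, not past fry, and 37.8% nearer to lemon, past fry, at a median position of 0.60. With all arrays on the probes called without it (698 with values), 54.3% were below and 33.1% nearer to lemon, neither past fry. With all 3 hybrid arrays, scale normalization between arrays gave 51.2% below and 37.3% nearer to lemon, neither past fry. For homogentisate geranylgeranyl transferase and chlorophyll a-b binding protein 151, each of the 3 hybrid arrays lay with mandarin. They also lay apart from all 3 lemon arrays, which the rule that named both genes in hybrid with lemon required.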

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

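The tests of a swap and of scan days, and the counts of splits for probes and lists between hybrid and mandarin and for probes against the mid-parent, were chosen after the result was seen. Some control spots outside the comparisons gave signal above that of empty and buffer spots, of which at most 0.765% of 392 lay well above background on any array. Of 30 spots of citrus tristeza virus proteins at least 3.33% did so on every array, up to 10%, with 1 spot on all 9. Of 10 spots the array list calls CTV-related at least 40% did so, up to 50%, with 3 on all 9. Of 33 yeast spots at least 3.03% did so, up to 36.4%.

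Hybrid 2 resembled the mandarin arrays. Its SD from the mean of a pair of mandarin arrays was 0.26 to 0.31, below the 0.36 to 0.47 of the mandarin arrays themselves. After a mandarin array was subtracted, its slope on the other hybrids' difference from mandarin was 0.0258, within the -0.0797 to 0.103 of mandarin arrays put in its place, so this array may hold mandarin RNA through a wrong label or an outside or repeated sample. All 3 mandarin arrays lay with mandarin (lowest median position 0.938). This cannot decide on a swap with a mandarin array, since these probes were chosen for agreeing across the arrays labelled mandarin. Over all probes the mandarin arrays correlated at 0.39 to 0.52 with each other and at most at 0.10 with hybrid 1 or hybrid 3. That goes against a swap, though hybrid 1 and hybrid 3 correlated at only 0.17 with each other. A shared scan day is argued against by a correlation of 0.516 with mandarin 2 of its own day. It lay below 0.649 and 0.613 with mandarin 1 and mandarin 3 of other days. A hybrid tree or fruit whose expression was like mandarin stays open and was not tested.

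Lemon 1 and hybrid 3 shared a pattern (r = 0.66 between their ratios across probes). The deviations of their Cy5 channel from the other arrays correlated at 0.502 and those of the Cy3 channel at 0.108. With Cy5 as the reference, as labelled, this argues against the sample RNA as the whole cause. The ratios of lemon 1 and of hybrid 3 correlated at -0.539 and -0.579 with the Cy5 deviations of the other array and at 0.304 and -0.0133 with its Cy3 deviations. By the labelled channels a difference in the reference of these arrays may therefore explain the pattern, though Cy5 deviations of other pairs correlated at up to 0.66. The group means far above the mix argue against the labelled channels. If Cy5 held the samples, the same values point to the sample RNA instead, so neither cause is settled. A shared scan day is argued against, since lemon 1 correlated at most at 0.311 with an array of its own day. A share of the sample RNA in the pattern, with which the 0.304 goes, and a biological likeness of these fruits in part of the probes stay open.

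The photosynthesis list was called as higher in mandarin than in lemon with the preset correlation and not with an estimated one (adjusted p = 0.565), and 6 of its 56 probes passed, all higher. Of the 10 brightest photosynthesis probes 2 were higher in mandarin by 0.5 or more on the log2 scale, fewer than predicted for a larger share of green peel. This cannot decide on peel. The 10 include rubisco subunit-binding proteins and ribulose-5-phosphate-3-epimerase, matched only by the words rubisco and ribulose, and none of the 10 passed. Of 19 epidermis and cuticle markers 3 were higher and 0 lower, with medians of 0.268 and 0.229 within scan days 1 and 2. By the labelled channels this goes with more peel in mandarin, and with the channels turned with less. Their list was not called (median 0.07, adjusted p = 0.197). The reference channel of lemon 1 is argued against by a list median of 0.276 without that array, still called with the preset correlation. A part played by peel, a difference between the parents in the expression of single photosystem genes, and other differences in fruit tissue all stay open.

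Other splits of the arrays were counted for each result. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. For mandarin with lemon 1 of the 10 splits, the real one, gave as many as 403 probes, and the highest other gave 0. For its lists 1 gave as many as 3, the highest other 2. For hybrid with lemon 1 gave as many as 89 probes, the highest other 8, and 1 gave as many as 4 lists, the highest other 1. For hybrid with mandarin the real split gave 0 probes and 0 lists, and the highest other 0 probes and 2 lists. No split can give fewer than 0, so these counts test nothing. Against the mid-parent the real split also gave 0 probes, so the 100 drawn splits could not test that count. The highest other gave 45, with lemon 1, hybrid 1 and hybrid 3 in the place of the hybrid, which points to a structure of the samples. For its lists 2 of 100 splits gave as many as the real 4, the highest other 4. Many drawn splits mix mandarin and lemon arrays, which differ, within a group, so they give no null for a hybrid at the mid-parent. They cannot decide whether chance gave that number, and with an estimated correlation no list was called. For the shares, only 6 of the 100 drawn splits called enough probes between their parent groups to be tested, too few for a share under 0.05. The remaining possible splits were not drawn. Of these, 3 gave a fry p as small as that of the 60% below the mid-parent (highest other share 67.6%) and 4 as small as that of the 15.1% nearer to lemon (highest other share 98.5%).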

How the results depend on the processing

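The alternatives with all flags ignored, with lemon 1 and hybrid 3 left out, with list patterns from the start of a word and with hybrid 2 and the probe set changed apart were chosen after the data were seen. The cause of a change was not tested unless it lies in fewer samples, fewer probes or a stricter threshold. Mandarin with lemon called 403 probes, and 2031 with array weights (lemon 1 had the lowest weight, 0.154), 907 without lemon 1 and hybrid 3 together, 680 with only these groups in the fit, 157 with the replicate number as a block, 71 with scan day as a block and 36 at an adjusted p under 0.01. The 9 counts with 1 array left out ran from 46 to 699. The replicate numbers did not pair the arrays: 3 of 9 correlated best with an array of their own number. Hybrid with lemon called 89 probes, and 217 with array weights, 227 without lemon 1 and hybrid 3, 11 with the replicate block, 10 at an adjusted p under 0.01, 9 with only these groups, and 0 with scale normalization or scan day as a block. With 1 array left out it called 10 to 175. Hybrid with mandarin called 0 in all other alternatives and 0 to 68 with 1 array left out, the 68 without hybrid 2. Hybrid with mid-parent called 0 with any 1 array left out, 1 with foreground means, 1 with print-tip loess and 2 with a linear mid-parent.

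The share below the mid-parent, which goes with the lean toward mandarin and the balance of the probes called, was 60% and passed fry. It did not pass at 51.2% with scale normalization, 54.3% with array weights, 56.7% with the replicate block, or 52.1% with all flags ignored. It was 78.4% with a linear mid-parent, which lies higher by construction. With 1 array left out it ran from 49.4% to 64.6%, and reversed without hybrid 2 (49.4%). It did not pass at 57.1% with hybrid 2 left out on the probes called with it, or at 54.3% with all arrays on the probes called without it. The share nearer to lemon was 15.1% and passed fry. It did not pass at 14.9% with median centring, 37.3% with scale normalization, 15.9% with probes above background on all arrays, 13.8% with the authors' values or 23.9% with array weights. It was 20.1% with a linear mid-parent, a value that depends on the channels. With 1 array left out it ran from 0% to 57.2%, and reversed without hybrid 2 (57.2%). It was 37.8% with hybrid 2 left out on the probes called with it, and did not pass at 33.1% with all arrays on the probes called without it, so the array and the probe set each moved it.

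Lists called were 3 in mandarin with lemon, 4 in hybrid with lemon and 4 against the mid-parent, and 0 in each with an estimated correlation. In hybrid with lemon 2 were called with probes above background on all arrays, 2 with the authors' values, 2 with array weights and 2 without lemon 1 and hybrid 3. Against the mid-parent it was 1 with scale normalization, 1 with probes above background on all arrays, 2 with the authors' values, 2 with array weights, 2 with scan day as a block and 1 without lemon 1 and hybrid 3. With 1 array left out, 2 to 4 were called in mandarin with lemon, 0 to 1 in hybrid with mandarin, 2 to 4 in hybrid with lemon and 1 to 4 against the mid-parent. The photosynthesis list against the mid-parent reversed without hybrid 2 (median -0.0105, otherwise up to 0.127 with 1 array left out).

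The 58 results of named genes past the threshold kept their direction in all 803 values of the other alternatives, and 96 of these missed the threshold. With 1 array left out 183 of 516 missed it. The 11 called lists kept their call in 130 of 176 values, and in 65 of 99 with 1 array left out. All other alternatives gave total counts within 1.5 times those reported, though the balance changed with scale normalization (153 higher and 134 lower in mandarin than in lemon, against 152 and 251). With the authors' values the median over all probes moved to -0.0725 at most. Signal over background limits the ratios of dim probes, which the offset draws toward 0.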

Other observations

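The values without hybrid 2 and those of the brightest photosynthesis probes were chosen after the data were seen. Without hybrid 2, hybrids 1 and 3 differed from mandarin in 68 probes, each displaced toward lemon and some of them beyond the lemon mean. For a xyloglucan endotransglycosylase (C05133B06) hybrids 1 and 3 had a mean of 3.51 and lemon 1.93. The genes named here were picked from the largest of these differences. Germin-like protein subfamily 1 member 13 was, by the labelled channels, higher than in mandarin by 4.99 ± 0.66 (31.8-fold, adjusted p = 0.0206), xyloglucan endotransglucosylase/hydrolase 23, an enzyme that rejoins wall polymers, by 4.34 ± 0.46 (20.3-fold), alcohol dehydrogenase by 4.29 ± 0.31 (19.5-fold), the cysteine protease vignain by 4.15 ± 0.50 (17.7-fold) and a senescence-associated rhodanese protein by 4.04 ± 0.55 (16.4-fold). Caffeic acid O-methyltransferase, of the lignin pathway, was lower (-2.98 ± 0.43), as were heat shock protein 70 (-2.69 ± 0.34), NADH-plastoquinone oxidoreductase subunit 3 (-2.33 ± 0.26) and the transcription factor MYB92 (-2.10 ± 0.28, with 2 mandarin and 2 lemon arrays). For germin-like protein 13 the means were -0.52 in mandarin, 3.80 in lemon and 4.47 in hybrids 1 and 3, with -0.94 in hybrid 2. Over the 68 probes called without it, hybrid 2 lay at a median of 0.081 between mandarin (0) and the other hybrids (1).

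Among the 10 brightest photosynthesis probes the parents differed in both directions, and none passed the test. A pair of rubisco small subunit probes, for the enzyme that fixes carbon dioxide, lay at -1.32 ± 0.51 (C31701G07, adjusted p = 0.186) and -1.22 ± 0.40 (C04032A01, adjusted p = 0.122) in mandarin against lemon. Photosystem II protein K (C16012B03) lay at 2.46 ± 0.98 (adjusted p = 0.196), and cytochrome b6-f complex subunit V at -1.98 ± 0.97 (adjusted p = 0.287).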
